A study of Homo sapiens with 6 samples.

How the data were processed

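Total RNA of MDA-MB-231 cells was labelled with biotin from 250 ng by a 3' in vitro transcription protocol and hybridised to Affymetrix U133 Plus 2.0 arrays, per the labels' protocols. Cells had been infected with pLKO.1 lentiviral vectors, selected in 1.0 µg/ml puromycin for 2 weeks and used at passage 2. The 6 arrays fell into 2 groups of 3 by their titles, shGFP control and shATAD3A knockdown, and 0 columns of the table were left unmatched.

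The deposited values are on a log2 scale, which was read from their range and shape, since the scale and the summary method were not given in the sources used here. Partek is named, without a version, per the submitters' processing notes. Array medians lay between 3.16 and 3.23, the lowest value was 0.826 and the highest 16.6. The values formed a low mode and a broad upper range, and the lowest point between them, 4.43, was used to describe genes as in or above the low mode. This boundary was chosen after seeing the data, and 47.4% of genes lay below it. Detection calls were not used here.

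Of the 54675 probe sets, 62 controls were set aside, 41091 had 1 gene symbol in the platform annotation of 2016, 1801 had several and 11721 had none. Symbols were checked through Entrez IDs against the GRCh38.p14 gene table, which updated 0 symbols and lacked the ID of 54 probe sets. For each gene the probe set with the highest mean over the 6 arrays was kept, among those with 1 symbol, with no filter on dim probe sets. The choice of probe set and test, the gene lists and the other settings to try were fixed before the data were examined.

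The groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided, no covariates) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. There were 22 gene lists and 5 lists of cell type markers, 27 in all. Genes named were ATAD3A, its paralogs ATAD3B and ATAD3C, WASF3 and HSPA5, and the 12 largest increases and 12 largest decreases among changed genes whose groups did not overlap. From each list, up to 2 of the largest increases and 2 of the largest decreases among changed members were named, or the member with the smallest p where none changed. Not every gene this rule takes is printed.

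The fit was tested on simulated data for the knockdown against control comparison over 19775 genes, of which 200 were changed. It recovered 28% of genes changed by 0.3 on the log2 scale, 56% at 0.5, 92% at 1 and 100% at 2. Of 147 calls, 9 were false (6.12%). The data gave 6644 calls, and the adjustment is less strict with more changed genes, so this recovery does not carry over to the data. Falls beyond 2-fold were tested with limma's treat, a test added after seeing the data. The most similar pair of arrays shared 0.0165% of their values, so no array was counted as a copy of another.

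Alternatives covered normalization, filters on dim probe sets, the probe set per gene, the variance prior, array weights, thresholds, the replicate number as a block, leaving out each replicate and the set test. Removal of the median of neighbouring genes (25 on either side) was added after seeing the data. Gene order was taken from the GRCh38.p14 table, which was used for names and for which genes are neighbours. Runs of genes were cut evenly within each chromosome to hold about 40 genes each; a first version of this step left runs of 1 gene through a rounding error and was corrected before its results were used. DNA copy number and GC content were not analysed here. The result of 1 control probe set is not reported here.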

Results

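MDA-MB-231 is an invasive, triple-negative breast cancer cell line. ATAD3A is an ATPase anchored in the inner mitochondrial membrane, where it is tied to mitochondrial DNA nucleoids, cristae and protein synthesis. RNA from cells carrying a stable short hairpin against ATAD3A was hybridised to 3 arrays, and RNA from cells carrying a hairpin against GFP to 3 more. The comparison asks which transcripts differ on average between cells with and without the ATAD3A hairpin. All values below are log2 expression values, changes are knockdown minus control, and errors are SD over n = 3 arrays or SE of the limma fit. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision.

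ATAD3A itself was lower in the knockdown arrays. Its value was 7.77 ± 0.038 (SD, n = 3) in control and 7.28 ± 0.21 (SD, n = 3) in knockdown, a change of -0.49 ± 0.105 (SE; limma adjusted p = 0.0129), or 29% lower. With the median change of neighbouring genes removed, a setting chosen after seeing the data, ATAD3A changed by -0.76 (adjusted p = 0.00244). That setting subtracts the neighbour median, 0.27, as a fixed value without error. The run of genes that holds ATAD3A, with a median of 0.25, lay within the range of shuffled gene orders. The larger fall is thus not evidence of a stronger knockdown. The knockdown arrays read 7.41, 7.03 and 7.39, all below the lowest control array at 7.73. These values come from the one probe set given to ATAD3A alone, of a type (x_at) whose probes may cross-hybridise with related transcripts. ATAD3B, a close paralog, changed by -0.30 ± 0.062 (SE; limma adjusted p = 0.0107) on its brightest probe set. Another ATAD3B probe set, at 7.46 in control, changed by -0.12 (adjusted p = 0.387). The brighter of the probe sets given to both genes changed by -0.26. These probe sets cannot be assigned with certainty to one of the paralogs. ATAD3C lay near the bottom of the scale in both groups, with a change of -0.025 (adjusted p = 0.722). WASF3, an actin regulator of the WAVE family, fell from 8.70 ± 0.097 to 8.29 ± 0.16 (SD, n = 3; limma adjusted p = 0.0155). The WASF3 call was lost without control replicate 1 (adjusted p = 0.0516) and without knockdown replicate 2 (adjusted p = 0.0532). HSPA5, the endoplasmic reticulum chaperone BiP, had a change of 0.12 on its brightest probe set, at 13.9 in control, that missed the threshold (adjusted p = 0.0511) and passed after quantile normalization (adjusted p = 0.031), with arrays centred on their medians (adjusted p = 0.0429), with averaged probe sets (adjusted p = 0.00117), with an intensity trend (adjusted p = 0.0383) and without control replicate 2 (adjusted p = 0.0348). Its other probe set, at 8.13 in control, rose by 0.42 (adjusted p = 0.00841).

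**Figure D1:**
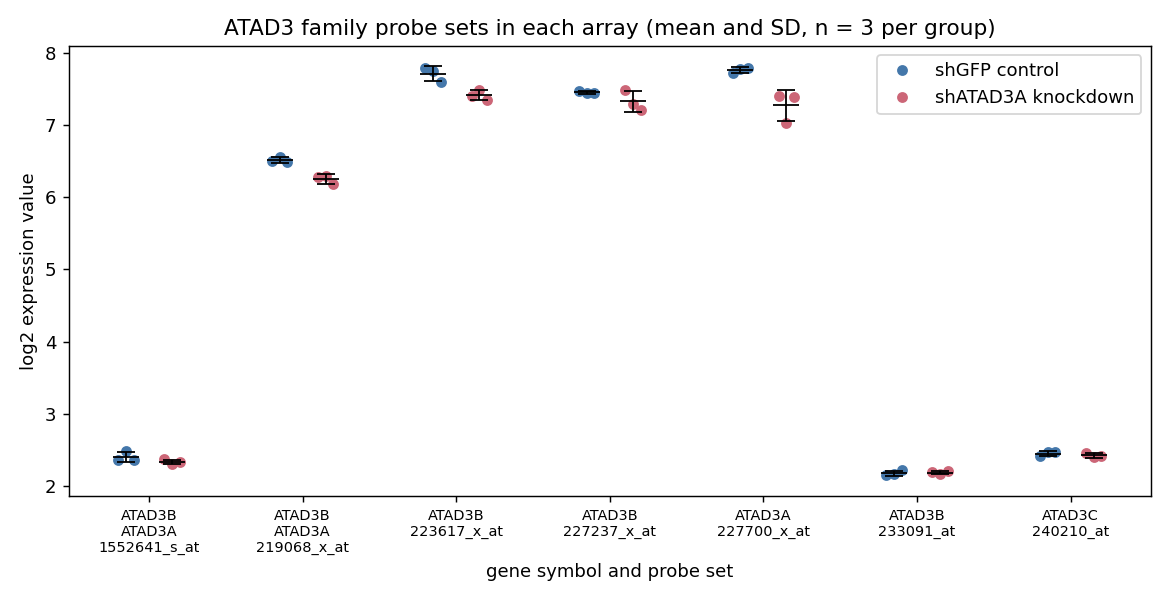
Each point is the log2 expression value of one array for a probe set of the ATAD3 family (shGFP control, blue; shATAD3A knockdown, red), with the mean and SD of 3 arrays in black. The probe set given to ATAD3A alone lies at 7.77 in control and 7.28 in knockdown, while 3 of the 7 probe sets lie near the bottom of the scale in both groups.

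The difference between the groups reached far beyond the targeted gene. Of 19775 genes, 6644 changed (33.6%), 3895 upward and 2749 downward, by limma at an adjusted p of 0.05. Among the 10400 genes above the low mode of the values, 6380 changed (61.4%). Most changes were small, with 59.5% of the changed genes under 1.5-fold, and 672 genes rose and 478 fell by at least 2-fold. Groups did not overlap for 42.0% of all genes, where chance gives 10%. At the level of probe sets, 12240 of 54613 changed. Correlations between arrays ranged from 0.9986 to 0.9991 within groups and from 0.989 to 0.9898 between them, across probe sets, which are not independent replicates.

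ID2, an inhibitor of helix-loop-helix transcription factors, rose from 5.15 ± 0.51 to 11.8 ± 0.12 (SD, n = 3), a change of 6.67. HKDC1, a hexokinase family member, rose by 6.42 and the protocadherin PCDH7 by 5.97. The small heat shock protein HSPB8 rose by 5.81. CYRIA rose by 5.79, DMKN by 5.52, SEL1L3 by 5.48, the protease inhibitor SLPI by 5.37 and ZG16B by 5.32. The calcium-binding protein S100P rose by 5.18. CDH1, which encodes E-cadherin, rose from 2.40 ± 0.044 to 7.53 ± 0.11 (SD, n = 3), a change of 5.13, and the adhesion molecule CEACAM1 rose by 5.13. The limma adjusted p of these 12 genes was between 3.755e-07 (HSPB8) and 1.207e-05 (ID2). The other probe sets of HSPB8, CDH1 and CEACAM1 lay in the low mode and were not called. Other probe sets of HKDC1, PCDH7 and CYRIA above the low mode also rose, by as little as 3.43, 2.85 and 3.64.

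CHRDL1, a bone morphogenetic protein antagonist, fell from 10.6 ± 0.051 to 4.77 ± 0.26 (SD, n = 3), a change of -5.84. TMEM163 changed by -5.77, the cystatin CST1 by -5.59, the TNF family ligand TNFSF15 by -5.49 and the endotoxin receptor TLR4 by -5.48. NAP1L3 changed by -5.46, the phosphodiesterase PDE1C by -5.34, the organic anion transporter SLCO4A1 by -5.26 and the atypical cadherin FAT3 by -5.19. PARM1 changed by -4.87 and INHBA, the activin A subunit, by -4.80. HMGN5 changed by -5.11, and its other probe set lay in the low mode, as did that of SLCO4A1. Other probe sets of TLR4 and PARM1 above the low mode also fell, with changes as small as -3.24 and -2.91. In all, 24 genes moved from the low mode in control to above 7 in knockdown, and 15 moved from above 7 in control to the low mode in knockdown. Values in the low mode hold little signal, so the folds of these and other genes with a group in the low mode are imprecise.

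Transcripts of the mitochondrial ribosome rose as a group. Of 73 measured members, 50 rose, 10 fell and 13 did not pass the test, or 51 and 11 adjusted over the list alone, with a median change of 0.33 (camera adjusted p = 2.122e-06; adjusted p = 0.396 with an estimated correlation). The small-subunit genes MRPS35 and MRPS26 rose by 1.03 and 0.93, while MRPS6 changed by -0.54. The median of this list was 0.21 when all probe sets of a gene were averaged (adjusted p = 8.6e-05). Subunits of respiratory complexes I to V went both ways: 34 of 68 rose and 11 fell, or 37 and 13 adjusted over the list alone (camera adjusted p = 0.00658; adjusted p = 0.672 with an estimated correlation). Their median change was 0.16, and 0.018 without probe sets of the s_at and x_at types (adjusted p = 0.26). The call was also lost with a milder filter on dim genes (adjusted p = 0.0517). ATP5F1D of ATP synthase rose by 0.81, and the complex I subunit NDUFB11 changed by -0.85. NDUFS7 rose by 0.94, and its other probe set lay in the low mode. Of 29 genes of the nucleoid and mtDNA upkeep, 13 rose and 1 fell, or 14 and 2 adjusted over the list alone (camera adjusted p = 0.00658; adjusted p = 0.396 with an estimated correlation). POLRMT rose by 1.07, with its other probe sets in the low mode and not called. MPV17 rose by 0.90 and the thymidine kinase TK2 was the 1 that fell, with -0.77. Of 45 genes for mitochondrial shape, cristae and import, 27 rose and 6 fell, or 28 and 8 adjusted over the list alone (camera adjusted p = 0.00292; adjusted p = 0.396 with an estimated correlation). TIMM22 of the inner membrane translocase rose by 0.91, and TIMM21 changed by -0.70. The median change of neighbouring genes was 0.53 around ATP5F1D and NDUFS7, 0.52 around POLRMT, -0.54 around NDUFB11 and 0.45 around TIMM22. Around MRPS35, MRPS26 and MRPS6 that median was 0.46, 0.40 and -0.36. These genes thus moved the same way as their neighbours. Around MPV17 and TIMM21 the median was 0.056 and -0.011, and around TK2, which fell, 0.29.

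Genes of the mitochondrial unfolded protein response rose in 11 of 18 cases and fell in 2, both over all genes and adjusted over the list alone (camera adjusted p = 0.04; adjusted p = 0.396 with an estimated correlation). The protease LONP1 rose by 0.69 and the chaperonin HSPE1 by 0.64. The 2 that fell were the import subunit TIMM17A, with -0.26, and the protease AFG3L2, with -0.24; AFG3L2 read 0.051 with the neighbour median removed. The nucleoid list above also holds HSPD1, HSPA9, LONP1 and ENDOG of this response. The shape and import list also holds GRPEL1, YME1L1, AFG3L2, SPG7 and TIMM17A, so the calls of these lists are not independent. The mitochondrial unfolded protein response list passed under 10 of 21 other settings. It missed the threshold without control replicate 3 (adjusted p = 0.058), without knockdown replicate 2 (adjusted p = 0.0977), after quantile normalization (adjusted p = 0.0584), with averaged probe sets (adjusted p = 0.0873) and on ranks (adjusted p = 0.0942). The endoplasmic reticulum list did not pass the set test (14 rose and 8 fell of 35, or 17 and 9 adjusted over the list alone; camera adjusted p = 0.147). SDF2L1 rose by 1.04 and HERPUD1 changed by -0.76. The ATF4 list did not pass either (11 rose and 10 fell of 38, or 13 and 11 adjusted over the list alone; adjusted p = 0.944). Its members moved far in both directions, with GDF15 up by 1.85, the cystine transporter SLC7A11 up by 1.41 and VEGFA and CTH changed by -1.84 and -1.68. The other probe sets of GDF15 lay in the low mode and were not called.

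Genes of the type I interferon response rose, 26 of 40 measured, with 6 lower and 8 not past the test, or 27 and 8 adjusted over the list alone. Their median change was 0.48 (camera adjusted p = 7.987e-06; adjusted p = 0.159 with an estimated correlation), and 0.86 without probe sets of the s_at and x_at types. OASL rose from 8.34 ± 0.11 to 11.5 ± 0.080 (SD, n = 3), a change of 3.11, and IFIT1, which binds viral RNA, rose by 2.62. IFITM1 changed by -1.66 and OAS2 by -1.10, while another OAS2 probe set gave -0.19 (adjusted p = 0.556). Genes of NF-κB and inflammatory cytokines fell in 13 of 31 cases and rose in 8, the same counts as adjusted over the list alone (camera adjusted p = 0.04; adjusted p = 0.396 with an estimated correlation). CSF3 and CXCL10 fell into the low mode in knockdown, with imprecise changes of -3.19 and -2.23. CXCL5 rose from the low mode in control by an imprecise 4.11, and the chemokine CCL20 rose by 2.89. This list passed under 12 of 21 other settings. It missed the threshold without control replicate 1 (adjusted p = 0.089), without knockdown replicate 1 (adjusted p = 0.134), with array weights (adjusted p = 0.114), with a milder filter on dim genes (adjusted p = 0.0517) and on ranks (adjusted p = 0.116). Immediate early genes fell in 18 of 33 cases and rose in 5, or 19 and 6 adjusted over the list alone (camera adjusted p = 0.00216; adjusted p = 0.261 with an estimated correlation). The phosphatase DUSP4 changed by -1.55, while the growth factor EREG rose by 4.31 and DUSP1 by 1.35.

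Epithelial genes rose in 19 of 38 cases and fell in 6, or 19 and 7 adjusted over the list alone, with a median change of 0.33 (camera adjusted p = 0.00658; adjusted p = 0.203 with an estimated correlation). The median was 1.02 without the dimmer genes, those below the median of mean expression (adjusted p = 0.115) and 0.048 without probe sets of the s_at and x_at types (adjusted p = 0.121), and the call was lost in both. It was 0.21 without knockdown replicate 2 (adjusted p = 0.013) and 0.18 with averaged probe sets (adjusted p = 0.00787). Beside CDH1, MAL2 rose by 3.05, while the claudin CLDN7 changed by -1.72 and the transcription factor EHF by -1.58. The luminal breast marker list moved the same way: 8 of 19 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.0262; adjusted p = 0.261 with an estimated correlation). The luminal call was lost without the dimmer genes (adjusted p = 0.115) and without probe sets of the s_at and x_at types (adjusted p = 0.121). It was also lost with a milder filter on dim genes (adjusted p = 0.0686). AGR2 rose by 2.60 and the receptor ERBB3 by 1.42, while the transcription factors GATA3 and XBP1 changed by -0.63 and -0.21. Another XBP1 probe set gave 0.28 (adjusted p = 0.176). Mesenchymal and matrix genes did not pass (12 rose and 15 fell of 50, or 12 and 16 adjusted over the list alone; camera adjusted p = 0.42), with COL4A1 and TGFBI up by 2.40 and 2.35 and the matrix protein TNC changed by -1.62. Its median was 0.0075 and its mean -0.033, so these differ in sign. Extracellular proteases and their inhibitors fell in 17 of 48 cases and rose in 7, or 18 and 7 adjusted over the list alone (camera adjusted p = 0.00216; adjusted p = 0.159 with an estimated correlation). Besides CST1, the metalloprotease ADAMTS1 changed by -2.90, and MMP16 rose by 1.74 from the low mode in control, with no other probe set above the low mode.

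Among growth genes, S phase and DNA replication genes rose in 21 of 47 cases and fell in 6, or 23 and 6 adjusted over the list alone (camera adjusted p = 0.00658; adjusted p = 0.396 with an estimated correlation). CCNE1 (cyclin E1) and POLE, a replicative DNA polymerase, rose by 1.06 and 1.05, while TYMS changed by -0.49. Genes of G2 phase and mitosis did not pass (16 rose and 12 fell of 61, or 16 and 13 adjusted over the list alone; camera adjusted p = 0.817). CDC25A rose by 0.95, with 0.39 (adjusted p = 0.0562) on another probe set, and the kinesin KIF4A changed by -0.88. The p53 list did not pass (10 rose and 7 fell of 29, also adjusted over the list alone; adjusted p = 0.944), with GDF15 up as given above, TIGAR up by 1.12 and the cell cycle inhibitor CDKN1A changed by -1.48. Its median was -0.0044 and its mean 0.042, so these differ in sign. The BCL2 family and death receptors did not pass (17 rose and 9 fell of 34, or 19 and 11 adjusted over the list alone; camera adjusted p = 0.41), with BIK up by 1.26 and TNFSF10 (TRAIL) changed by -1.23.

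The other lists did not pass the set test, although single members moved. Of 39 genes of glycolysis and hypoxia, 18 rose and 11 fell, also adjusted over the list alone (camera adjusted p = 0.423), with EPAS1 up by 1.68 and BNIP3L and NDRG1 changed by -2.07 and -1.88. Of 35 genes of the WAVE and Arp2/3 machinery, 11 rose and 8 fell, also adjusted over the list alone (adjusted p = 0.901), with PFN2 up by 1.81 and DIAPH2 changed by -1.25. The median of that list was -0.0017 and its mean 0.06, so these differ in sign. Of 41 genes of autophagy and lysosome, 12 rose and 11 fell, or 13 and 13 adjusted over the list alone (adjusted p = 0.901), with MITF up by 1.20 and WIPI1 changed by -1.13. The test leaned down for that list, while its median and mean were 0.038 and 0.023. Of 29 genes of cholesterol synthesis, 13 rose and 7 fell, or 15 and 8 adjusted over the list alone (adjusted p = 0.467), with DHCR7 up by 0.86 and LPIN1 changed by -0.90. Of 43 cytosolic ribosomal proteins, 5 rose and 3 fell, or 3 and 2 adjusted over the list alone (camera adjusted p = 0.423), with RPL36 up by 0.37 and RPL31 changed by -0.23 on a probe set at 15.6 in control. Other RPL31 probe sets, at 10.4 in control, gave -1.69 (adjusted p = 4.835e-05) and -0.66 (adjusted p = 0.000234).

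Of 15 fibroblast markers 2 rose and 0 fell, or 1 and 0 adjusted over the list alone (camera adjusted p = 0.944). COL1A1 rose by 1.01, while another of its probe sets gave -0.37 (adjusted p = 0.152), and the median of the list was -0.009 and its mean 0.095, which differ in sign. Of 15 leukocyte markers 1 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.0514), with the HLA class II chain HLA-DRA changed by -3.75 and its chaperone CD74 by -3.45. These 2 were the only leukocyte markers above the low mode, so the result of this list rests largely on them. The setting without the dimmer genes kept only these 2. The leukocyte list passed, downward, with arrays centred on their medians (adjusted p = 0.0415), with an intensity trend (adjusted p = 0.0426), with array weights (adjusted p = 0.0415) and without the dimmer genes (adjusted p = 0.0156). It also passed without control replicate 2 (adjusted p = 0.0402) and without knockdown replicate 1 (adjusted p = 0.0326). Of 9 keratinocyte markers 1 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.518), with SFN up by 0.99 and S100A2 changed by -1.44. Of 9 erythroid and hepatocyte markers 0 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.548), with SERPINA1 changed by -3.91, and by -4.70 (adjusted p = 1.247e-05) on its other probe set above the low mode. Above the low mode lay 1 of the fibroblast, 2 of the keratinocyte and 1 of the erythroid and hepatocyte markers. Changes of the other markers are near background.

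**Figure D2:**
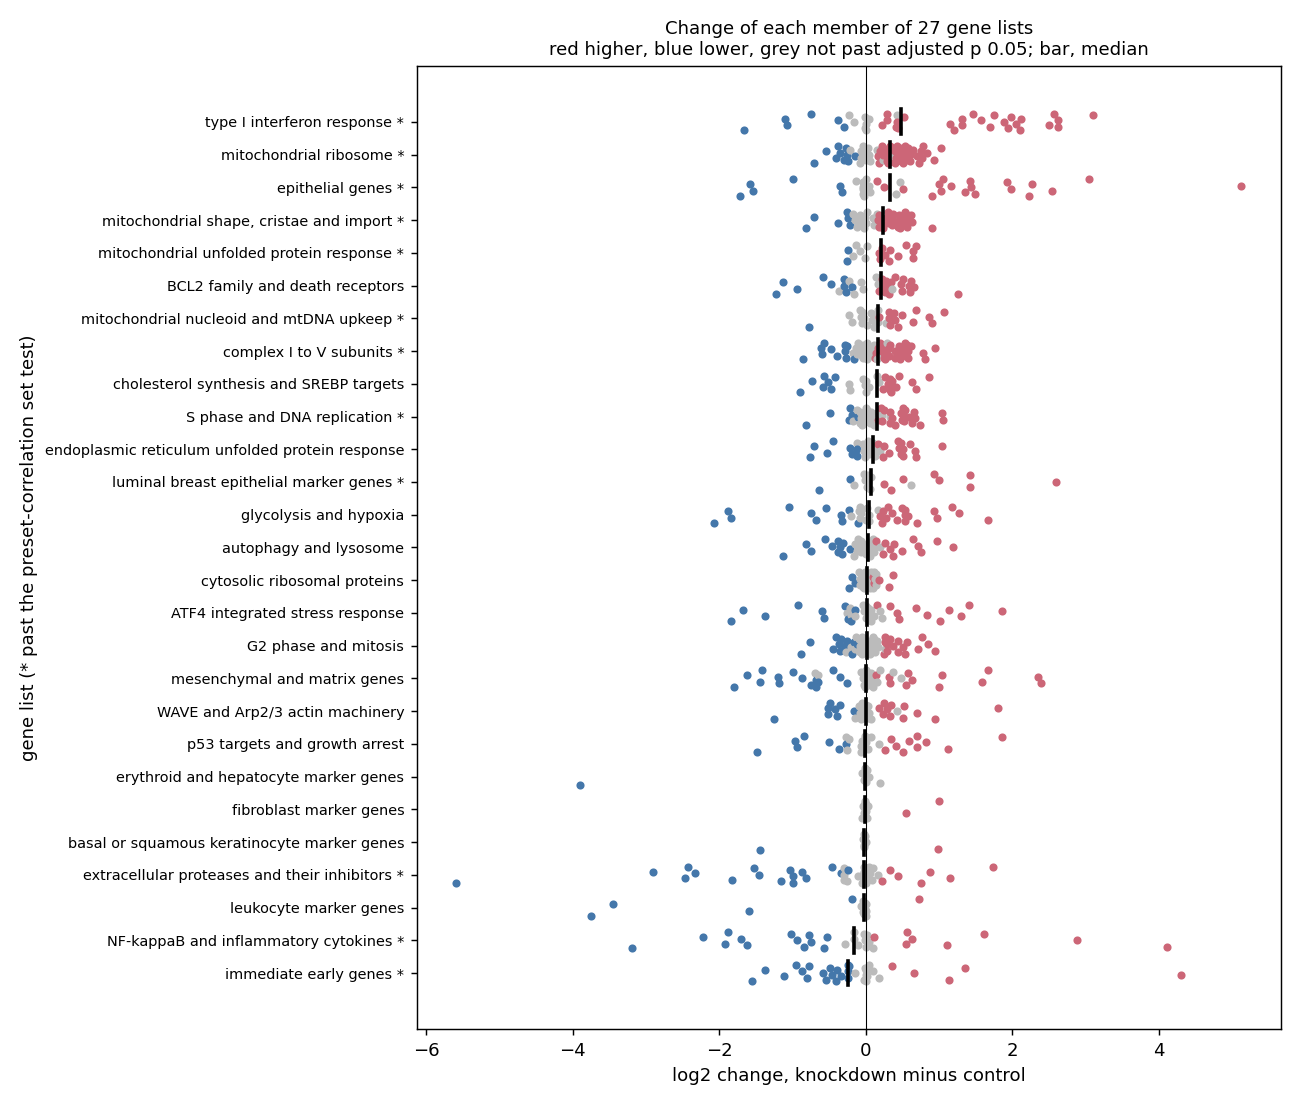
Each point is the log2 change (knockdown minus control) of one measured member of a gene list, coloured red if higher, blue if lower and grey if not past an adjusted p of 0.05; black bars are list medians and asterisks mark the 12 lists past the set test with its preset correlation. The type I interferon list has the highest median, 0.48, and the immediate early genes the lowest, -0.24.

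Of the 27 lists, 12 passed with the preset correlation, 9 upward and 3 downward, and 0 passed with an estimated correlation. Some lists share members, so these calls are not independent. When the 6 arrays were split in other ways that mix the groups, up to 19 lists passed the same test. Of the 10 splits, the real one included, 2 gave at least 12. Mixed splits still hold part of the group difference, so they do not show what chance alone gives. Leaving out the dimmer genes ended the call of 8 of the 12 lists: complexes I to V, nucleoid, shape and import, mitochondrial unfolded protein response, NF-κB, epithelial, S phase and luminal genes. Leaving out probe sets of the s_at and x_at types ended 7 of them, all of these but S phase.

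The changes also followed the order of genes along the chromosomes, a measurement chosen after seeing the data. Among 10383 genes above the low mode, ordered by the GRCh38.p14 annotation, the changes of neighbouring genes correlated with a Spearman rho of 0.288 across genes, against -0.034 to 0.031 in 1000 shuffled orders. Of 248 runs of about 40 genes, 11 had a median above and 18 a median below the range of shuffled orders. On chromosome 12, 5 runs lay above it, and on chromosomes 6 and X, 5 and 6 runs lay below it. Chromosome X also held the run with the highest median, 0.80 over 42 genes. Medians over whole chromosomes were 0.35 on chromosome 12, -0.20 on chromosome 6 and -0.50 on chromosome X. With the median of neighbouring genes removed, 3126 genes were higher and 3089 lower, a share of higher calls of 50.3% in place of 58.6%; this removal centres the changes locally, so it moves the share toward 50% by construction. The S phase list then missed the threshold (adjusted p = 0.118), while the mitochondrial ribosome list still passed (adjusted p = 4.352e-08). Of the genes named above, ATP5F1D (adjusted p = 0.0681), DIAPH2 (adjusted p = 0.0653), TYMS (adjusted p = 0.0771) and RPL36 (adjusted p = 0.117) missed the threshold under that setting. AFG3L2 changed sign under it, as given above.

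**Figure D3:**
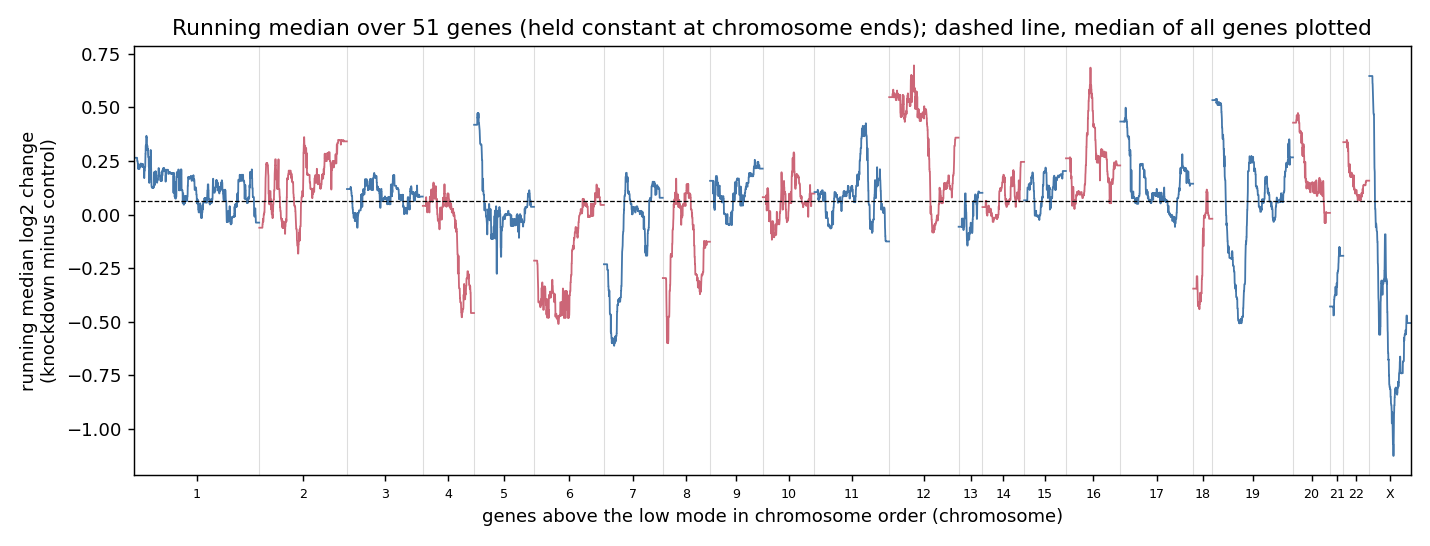
The line is the running median of the log2 change (knockdown minus control) over 51 genes above the low mode, in chromosome order, with colours alternating between chromosomes and a dashed line at the median of all genes plotted, 0.064. The line lies above the dashed line over much of chromosome 12 and below it over much of chromosome X, whose medians are 0.35 and -0.50.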

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

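The tests on gene order, on the low mode and on the mitochondrial ribosome were chosen after their results or related ones had been seen, except the comparison of arrays within their group; the counts over other splits were planned.

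Probe sets outside the gene-level comparison also passed the test, in both directions. Among probe sets without a gene symbol, 511 were higher and 696 lower of 11721 tested. Among probe sets with several symbols, 295 were higher and 203 lower of 1801.

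The first pattern is that changes of neighbouring genes move together (rho 0.288). Related neighbours with shared probes are argued against, since rho was 0.276 between neighbours of different symbol stem. Trends with gene density, length or mean expression are too, since rho was 0.277 without them. So is noise that differs between arrays of a group, since the highest rho of an array against others of its group was 0.0667. A technical difference shared by all arrays of a group cancels out of that comparison and stays open. A candidate explanation is that the 2 cultures differ in the dosage of chromosome stretches. In the 8 of 248 runs picked as outside the shuffled range on every other gene, 92.1% of the 165 genes left out lay on the run's side. Any cause that moves neighbours together would give such a share, so this value cannot tell dosage from other causes. Regional control of expression is one of these, and DNA was not analysed here. Whether the hairpin, the selection or an earlier difference between cultures brought the pattern about was not tested.

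The second pattern is that 24 genes moved from the low mode to above 7 and 15 the other way. A minority of other cells added to control-like cells is argued against as the whole cause, since dilution by a minority lowers no gene by more than 2-fold, and 235 of 10371 genes above the low mode in control were lower by more than that (limma treat, adjusted p of 0.05). Another cell line stays open. MDA-MB-231 is known to have lost MTAP, and the highest MTAP value in a knockdown array was 2.77, but no array here showed that these probe sets can measure the gene. A biological effect of the knockdown may also produce such changes and was not tested apart from the culture.

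The third pattern is the rise of the mitochondrial ribosome list. A trend with mean expression is argued against, since its median of 0.335 lay above the range of -0.049 to 0.168 of matched lists. Shifts shared with neighbouring genes are argued against as the whole cause, since the median was 0.211 with the neighbour median removed. The set test with an estimated correlation, adjusted p = 0.396, leaves open how far genes that vary together set this call. Grouped by symbol stem among genes above the low mode, MRPL and MRPS genes did not pass over 172 families (camera adjusted p = 0.234 and 0.239). Among the other called lists, nucleoid genes (median 0.172) lay within their matched range of -0.097 to 0.25. So did the mitochondrial unfolded protein response (0.205, range -0.124 to 0.244), S phase (0.159, -0.069 to 0.198) and luminal lists (0.073, -0.041 to 0.113). For these, a trend with mean expression stays open. The remaining called lists lay outside their matched ranges.

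The 6 arrays make 10 splits, too few for a share under 0.05. The real split gave 6644 changed genes, 3895 higher, 2749 lower and 12240 probe sets. Each count was reached in 1 of 10 splits, and the highest of the other splits gave 0 for each. All other splits mix the groups, so a large group difference enters their spread within groups and itself keeps calls few. These counts therefore cannot separate the group difference from chance. For gene lists, 2 of 10 splits gave at least the 12 of the real split. The highest other gave 19, in a split that mixes the groups. Mixed splits still hold part of the group difference, so they do not show what chance alone gives.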

How the results depend on the processing

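The neighbour correction and the boundary of the low mode were chosen after seeing the data; the other alternatives were planned. The pseudocount alternative was not run, since values are log2, ATAD3A has no value without _s_at and _x_at probe sets, and robust hyperparameters and the 2-fold threshold have no set test.

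Changed genes numbered 4845 to 7017 over the alternatives other than the 2-fold threshold, which left 1150 genes (672 higher, 478 lower) and 2233 probe sets by its construction. Without _s_at and _x_at probe sets, 7249 probe sets changed, as fewer were tested. ATAD3A kept its direction wherever it was measured, with -0.7593 when the neighbour median was removed, and its -0.4942 missed the stricter adjusted p of 0.01 and the 2-fold threshold. Leaving out each replicate gave 5845 to 6457 changed genes, 3390 to 3870 higher, 2444 to 2587 lower, 10410 to 11725 probe sets, 11 to 13 lists and ATAD3A changes of -0.5594 to -0.371. The numbers of lists past the set test were 5 without the genes below the median of mean expression, 5 without _s_at and _x_at probe sets, 0 with an estimated correlation, 20 with directional fry and 27 with mixed fry; the cause was not tested. The first of these settings lost 8 of the 12 lists and gained the leukocyte markers, of which it kept only HLA-DRA and CD74. Fry does not compare a list with other genes.

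Same-numbered arrays had correlations of -0.255, -0.175 and 0.0651 between their deviations, so the numbers do not pair arrays. With the replicate block, 6057 genes (3513 higher, 2544 lower), 10773 probe sets and 11 lists passed, and ATAD3A changed by -0.4942. The mitochondrial unfolded protein response list then had an adjusted p of 0.0518.

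XBP1 read 0.03499 as the mean of its probe sets, which differ in sign. Without _s_at and _x_at probe sets the sign turned where the probe sets left lie in the low mode, and such values near 0 are background: ATAD3B read 0.00835, NDUFS7 -0.0042, POLRMT -0.01165, GDF15 -0.0286, ULK2 -0.01421 and LUM -0.01174. With the neighbour median removed APOOL read 0.1116, AFG3L2 0.05113, RPS15 -0.2292 and RPL10A 0.2791, as the median removed was larger than the change. That setting gave 6215 changed genes, 50.3% of them higher (its centring draws this toward 50%), and shared 5114 with the 6644, of which 4943 had the same direction. Signal over background limits the genes in the low mode. Other probe sets of MRPS26, HERPUD1, TNC, CCNE1, EPAS1, DUSP1, GATA3, RPL36 and CD74 also lay there and were not called. The change of each of these genes thus rests on a single probe set.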

Other observations

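HLA class II genes, which present antigen on the cell surface, were lower in knockdown as a family, a pattern found by grouping all genes above the low mode by symbol stem after seeing the data. Of 9 genes whose symbols begin HLA-D, 8 fell and 0 rose, with a median change of -2.92 (camera adjusted p = 3.14e-05 over 172 families; adjusted p = 0.993 with an estimated correlation). HLA-DRA went from 11.9 ± 0.022 to 8.13 ± 0.13 (SD, n = 3), HLA-DPA1 changed by -3.17 and HLA-DMA by -2.42. HLA-DOB, with a change of -0.15, did not pass (limma adjusted p = 0.384). At 4.79 in control, HLA-DOB lay close to the low mode and could hardly show a fall. The 8 include the paralogs HLA-DRB1, HLA-DRB4 and HLA-DRB6, whose probe sets were not checked for cross-hybridisation. CIITA, the transcriptional activator of this family, changed by -2.76 (limma adjusted p = 0.000276). The genes around HLA-DRA had a median change of -0.44, far smaller than its own -3.75. HLA-DRA and CD74 are 2 of the 4 leukocyte markers that fell. No other family of at least 8 genes passed. The mitochondrial ribosome families missed the threshold in this comparison among genes above the low mode. Of 49 MRPL genes 33 rose and 6 fell (camera adjusted p = 0.234). Of 27 MRPS genes 19 rose and 4 fell (camera adjusted p = 0.239).

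Control probe sets differed between the groups in both directions. With 3 arrays per group an exact permutation p cannot fall below 0.1. The adjusted p of at least 0.15 over 9 tests thus cannot show that the groups were alike. The dap poly-A spikes, RNA added to each sample, differed by -0.28, from 9.38 ± 0.035 in control to 9.10 ± 0.026 (SD, n = 3) in knockdown. An 18S rRNA probe set differed by -0.33, and the hybridisation spikes by 0.12. The lys, phe and thr spikes differed by -0.083 and the GAPDH 3' probe set by 0.22. Each of these had an exact permutation p of 0.1, the smallest possible. The ACTB 3' probe set differed by -0.046 (exact permutation p = 0.2). The difference between the 3' and 5' probe sets moved by -0.012 for GAPDH and -0.13 for ACTB. The dap and 18S differences were similar in size, though not in sign, to the median change of the mitochondrial ribosome list, 0.33.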
